A study of Mus musculus with 18 samples.

How the data were processed

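RNA was measured in primary fibroblasts from tail tips of 2-month-old mice at passage 5, transduced by spinfection with lentivirus in 4 µg/ml polybrene. Per the labels, over 80% of cells were positive for the mCherry marker, there was no sorting or selection, and total RNA was extracted without a DNase digestion. There were 3 genotypes, 3 treatments and 2 mice per genotype, so 18 libraries from 6 mice. For 1 of the heterozygous mice the labels do not say whether the name stands for 1 animal or a pool. Per the submitters' processing notes, reads were checked with FastQC 0.11.2, aligned to mm10 with STAR 2.4.0k and quantified with HOMER. FPKM values were made by the authors with HOMER over exons, per the file headers with the parts of each transcript kept apart, so that the deposited table holds 404759 parts of 36795 transcripts. The lengths of parts in bases, another unit of the deposited table, were taken per the file headers. The protocol's strand was not stated, so antisense or overlapping transcripts cannot be separated.

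The table has 24 library columns. Those of the 18 labelled samples were used, and 6 columns that match no labelled sample were not used. The design had assumed rows of genes, and the transcript parts were combined into transcripts by length before anything else was done. Transcripts were named from the RefSeq table (36474) and GENCODE metadata (194), 127 stayed without a symbol, and for each of 24445 symbols the transcript with the highest mean FPKM was used. Depth was recovered from the steps of the values: 100% of the values tested in each library were whole multiples of a step within a tolerance of 0.05, which gave 22424416 to 42622080 reads per library. Whether a step is a read or a fragment cannot be told from the table.

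Genes with at least 1 FPKM in at least 2 libraries were tested, 12599 in all, on log2(FPKM + 1). This pseudocount makes fold changes of genes with low values smaller than the ratio of their means. Tests were made with limma 3.58.1 (lmFit, trended eBayes) in R 4.3.3, and the tables and figures with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Guide effects and their differences between genotypes were fitted on all 18 libraries with the mouse as a fixed block, which left 6 residual degrees of freedom. Libraries were paired by mouse, as the labels name them. The correlation of libraries within these pairs, after group means were removed, lay between −0.02 and 0.78 in homozygous Cas9 cells, 0.47 and 0.73 in heterozygous cells and 0.18 and 0.59 in wild-type Cas9 cells. Genotypes were compared in the 6 gMock libraries, which left 3 residual degrees of freedom. All p-values rest on 2 mice per genotype. They were adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Adjusted p-values are the ones given.

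Of 20 gene lists written beforehand, 19 were tested: lamins and nuclear envelope, p53 targets, senescence and secretory factors, cell cycle, extracellular matrix, interferon response, NF-kB, NRF2 targets, unfolded protein response, contractile genes, posterior Hox genes, and markers of fibroblasts, adipocytes, cartilage and bone, skeletal muscle, keratinocytes, endothelium, immune cells and pigment and Schwann cells. Sex-linked genes were kept as values per mouse. The 16 lists with at least 5 tested members went through camera (correlation 0.01, and again with an estimated correlation) and fry, adjusted over these lists. Named genes were chosen by a rule fixed beforehand: Lmna, up to 8 higher and 8 lower genes with the largest change among those that passed, with a mean of at least 2 FPKM and the same direction in both mice, without sex-linked genes and gene models, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p were named. Tmem119, Ctsh, Snord95, Mir7025, Mki67, Lyz2 and some further members of lists and of antigen presentation are named outside this rule. Members named for the difference between the guides, and for single guides in homozygous Cas9 cells, follow the list rule, applied after the data had been seen.

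Parts of Lmna were examined after the data had been seen. Exons 4 to 9 are shared by lamin A and lamin C. Use of parts within genes was tested with limma diffSplice and then, because no Lmna part had passed, with each part minus the gene's median part in the same limma fits. Parts of at least 50 bases with at least 5 FPKM in at least 9 libraries were kept, in genes with at least 3 such parts. Both results were adjusted over all parts and then over the parts of Lmna alone. The change of the exon 12 ratio was compared between mice with and without Cas9 by an exact permutation over the 6 mice. The effects of guides and genotype were correlated over genes with no shared library, beside 100 simulations without an effect.

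The fits were tested on simulated data, in which 200 of 12599 genes were changed. At a log2 change of 1, 90% were recovered for the guide effect in homozygous Cas9 cells with 7 false calls, 87% for a single guide with 12, 79% for a difference of guide effects with 8 and 46% for a genotype contrast with 10. At a change of 2 the shares were 100%, 99%, 98% and 91%. In simulated parts, diffSplice recovered 71% of the 200 changed parts with 72 calls in genes without a changed part, and the second part test 7.5% with 2 such calls. In simulated lists the moved list was found (adjusted p = 1.9e-61), with 1 other list. All these simulations drew genes or parts independently, each with the same spread in every library. They could not show how calls hold up where genes vary together or where the spread differs between genotypes.

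Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-ratio rescaling, quantile normalization, eBayes without trend, every transcript as its own feature, no mouse block, the mouse as a random effect, fits to the compared genotypes alone, and each library left out in turn. For genotypes they were means per mouse, all 18 libraries with a random mouse effect, and a block for the style of sample names. Alternatives added after the data were seen were limma voom on recovered reads, all parts of a symbol together, genotype contrasts in the libraries of each Lmna guide, and fits without heterozygous replicate 2 or without the interferon list. The alternatives planned for a table of counts were not run, as the table holds FPKM.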

Results

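RNA was sequenced from primary fibroblasts grown from the tail tips of 2-month-old mice. The series concerns a CRISPR/Cas9 treatment in mice with progeria, a premature ageing disorder caused by a mutant Lmna allele, written Pro in the sample names. There were 3 genotypes: Pro/Pro;Cas9/+ (homozygous Cas9 cells), +/+;Cas9/+ (wild-type Cas9 cells) and Pro/+; +/+ (heterozygous cells without Cas9, named as a negative control). Cells of each mouse were transduced by lentivirus with a mock guide RNA that has no genomic match (gMock) or with either of 2 guides against Lmna, gLmna-1 and gLmna-2. Each of the 3 treatments was given to cells of the same 2 mice per genotype, named replicate 1 and replicate 2 below. This made 18 libraries from 6 mice, with 2 libraries in each group. Values for both guides together hold 2 libraries from each of the 2 mice, so their n counts libraries, not mice. The libraries held 22424416 to 42622080 reads, as recovered from the steps of the expression values. A total of 12599 genes were tested.

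The targeted gene was examined first. Lmna, which encodes lamin A and lamin C of the nuclear lamina, was at 308 ± 87.7 FPKM (SD, n = 2) under gMock in homozygous Cas9 cells and at 256 ± 38.9 (n = 4) with the guides, a log2 change of −0.25 (SE 0.15, adjusted p = 0.74). It was at 349 ± 45.3 (n = 2) and 299 ± 25.5 (n = 4) in wild-type Cas9 cells, a log2 change of −0.22 (SE 0.15, adjusted p = 0.76). In heterozygous cells without Cas9 it was at 239.6 ± 4.54 (n = 2) and 237 ± 40.1 (n = 4), a log2 change of −0.03 (SE 0.15, adjusted p = 1.00). None of these differences passed the test. The change with gLmna-1 alone in homozygous Cas9 cells was −0.37 (adjusted p = 0.29) and became −0.70, past the threshold, when the gLmna-1 library of replicate 1 was left out. Without gMock of replicate 2 the change with the guides was 0.013 in place of −0.25. In homozygous replicate 1 Lmna was at 246, 249 and 247 FPKM with gMock, gLmna-1 and gLmna-2. In homozygous replicate 2 Lmna was at 369.8, 217 and 310, so the lower mean of the transcript used here came from 1 mouse. All these values are those of the Lmna transcript with the highest mean FPKM, which did not follow the lamin A end of the gene in every mouse. The exon 12 untranslated region of lamin A was lower with both guides in both homozygous mice. With gMock, gLmna-1 and gLmna-2 this region was at 114, 69.0 and 76.6 FPKM in replicate 1 and at 148, 56.2 and 63.3 in replicate 2. Group means of the other Lmna transcripts are given without a test. In homozygous Cas9 cells they were 223 and 284 FPKM under gMock, 154 and 214 with gLmna-1 and 184 and 257 with gLmna-2. In wild-type Cas9 cells they were 263 and 327, 204 and 274, and 212 and 280 in the same order. In heterozygous cells they were 182 and 221, 201 and 248, and 162 and 196.

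The table lists parts of transcripts, so the lamin A end of Lmna was compared with exons that lamin A and lamin C share. Lmna lies on the minus strand of chromosome 3 (mm10). The exon 12 untranslated region of lamin A spans 88481148 to 88482073, the lamin A exon 11 spans 88482346 to 88482612, and the untranslated end of lamin C spans 88483205 to 88483296. The ratio of the exon 12 untranslated region to the mean of exons 4 to 9 was 0.397 ± 0.0358 (SD, n = 2) under gMock in homozygous Cas9 cells, 0.248 ± 0.0118 (n = 2) with gLmna-1 and 0.238 ± 0.0686 (n = 2) with gLmna-2. In wild-type Cas9 cells the ratio was 0.400 ± 0.0191, 0.275 ± 0.00408 and 0.307 ± 0.0309 in the same order (n = 2 each). In heterozygous cells without Cas9 it was 0.457 ± 0.0112, 0.440 ± 0.0472 and 0.479 ± 0.0226 (n = 2 each). All 8 differences from gMock within a Cas9 mouse were negative, between −48.9% and −20.4%, and the 4 within mice without Cas9 lay between −12.7% and 6.4%. Both guides of a mouse were set against the same gMock library, so the 8 come from 4 mice and are not independent. An exact two-sided permutation test over the 6 mice gave a difference of −0.59 (log2, 4 Cas9 mice minus 2 without) and p = 0.0667, the smallest value this design allows. Genotype differs along with Cas9 in that test.

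**Figure D1:**
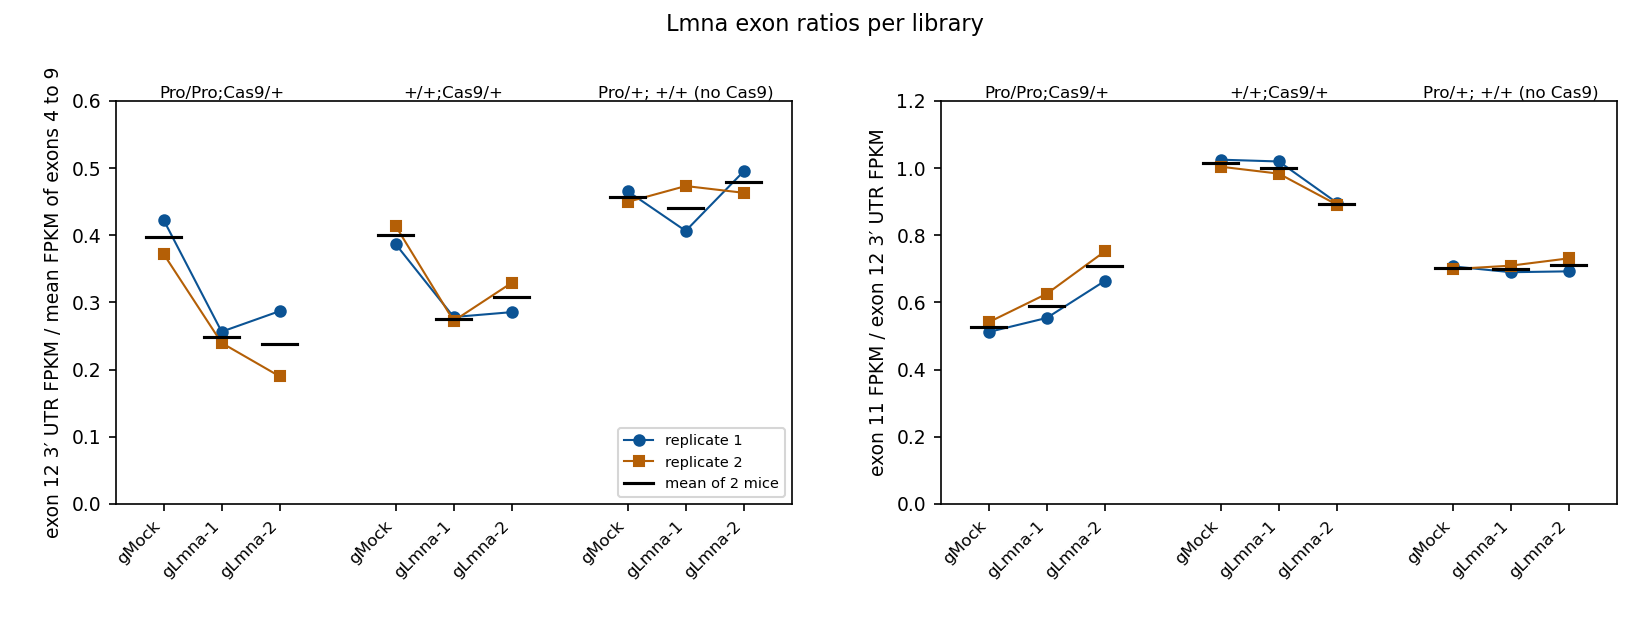
Left, ratio of the FPKM of the Lmna exon 12 untranslated region to the mean FPKM of exons 4 to 9 in each library, by genotype and guide. Right, ratio of exon 11 to the exon 12 untranslated region. Points are libraries, coloured lines join libraries of the same mouse and black bars are means of 2 mice; the left ratio lies at 0.423 and 0.372 under gMock in homozygous Cas9 cells and at 0.190 to 0.287 with the guides.

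The lamin C untranslated end, relative to exons 4 to 9 of Lmna, differed from gMock by 92.3% and 58.6% in homozygous replicate 1 and by 5.3% and 25.2% in homozygous replicate 2 with gLmna-1 and gLmna-2. The differences were 31.6% and 27.9% in wild-type replicate 1, 6.0% and 6.3% in wild-type replicate 2, and 5.7% to 16.8% in the mice without Cas9. Under gMock the ratio of exon 11 to the exon 12 untranslated region was 1.014 ± 0.0148 (SD, n = 2) in wild-type Cas9 cells, 0.703 ± 0.00562 (n = 2) in heterozygous cells and 0.527 ± 0.0207 (n = 2) in homozygous Cas9 cells. Exon 11 against exons 4 to 9 was lower than under gMock in all 8 guide libraries of Cas9 mice, by −34.4% to −11.9% in homozygous and −35.5% to −28.4% in wild-type cells, and differed by −14.8% to 7.7% in heterozygous cells. With the guides the ratio of exon 11 to the exon 12 region differed from gMock by 8.2% to 38.9% in homozygous Cas9 cells, by −12.5% to −0.5% in wild-type Cas9 cells and by −2.4% to 4.6% in heterozygous cells. These values rest on 1397 to 4483 reads per library over the exon 12 region, 244 to 1241 over exon 11 and 228 to 574 over the lamin C end. The ratios and their tests were chosen after the data had been seen.

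Use of Lmna parts within the gene was then tested across 91468 parts of 8297 genes, and no Lmna part passed in any comparison. The first test was limma's diffSplice, in which the exon 12 untranslated region differed by −0.71 (log2, SE 0.19) from the rest of Lmna with the guides in homozygous Cas9 cells (adjusted p = 0.30 over all parts, rank 102). The second, run after that result, took each part minus the gene's median part and gave −0.65 (SE 0.14, adjusted p = 0.81, rank 142). That second test called 0 parts of any gene in any comparison and recovered 7.5% of changed parts in simulated data. Not passing it over all parts therefore says little about Lmna. Adjusted afterwards over the 15 Lmna parts alone, the first and second tests gave adjusted p = 0.0050 and 0.020 for exon 12. In wild-type Cas9 cells the exon 12 values were −0.42 and −0.45 (adjusted p = 0.24 and 0.086 over Lmna parts alone), and in heterozygous cells −0.01 and 0.02. Exon 11 gave −0.52 and −0.55 in wild-type Cas9 cells (adjusted p = 0.11 and 0.068 over Lmna parts alone) and −0.40 and −0.36 in homozygous Cas9 cells (adjusted p = 0.20 and 0.17). The difference of guide effects itself did not pass for Lmna exon 12 even over Lmna parts alone. Homozygous minus heterozygous cells gave −0.70 and −0.67 (adjusted p = 0.17 and 0.12), and wild-type minus heterozygous cells −0.40 and −0.47 (adjusted p = 0.86 and 0.32). Exon 11 of Lmna in homozygous against wild-type Cas9 cells under gMock gave −0.93 and −0.98 (adjusted p = 0.97 and 0.86 over all parts, 0.034 and 0.0096 over Lmna parts alone).

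The guides were compared with gMock in homozygous Cas9 cells to find the response where Cas9 and the Pro allele are both present. Frzb and Sfrp1, secreted antagonists of Wnt signalling, rose from 2.23 ± 0.150 FPKM (SD, n = 2) to 6.45 ± 2.38 (n = 4; log2 change 1.15, SE 0.13, adjusted p = 0.023) and from 14.7 ± 8.15 to 32.3 ± 17.6 (1.02, SE 0.12, adjusted p = 0.023). Adam33, a membrane metalloprotease, rose from 2.18 ± 1.51 to 5.79 ± 2.55 (1.10, SE 0.07, adjusted p = 0.0011). Mfap5, a microfibril protein, rose from 81.7 ± 52.9 to 142 ± 51.6 (0.88, SE 0.11, adjusted p = 0.032), and Col14a1, a fibril-associated collagen, from 1.18 ± 1.18 to 2.92 ± 1.54 (0.87, SE 0.10, adjusted p = 0.023). Cd248, a stromal surface glycoprotein, rose from 27.8 ± 11.7 to 49.7 ± 11.2 (0.85, SE 0.10, adjusted p = 0.023) and Serping1, the C1 esterase inhibitor, from 14.4 ± 2.63 to 27.8 ± 11.4 (0.84, SE 0.10, adjusted p = 0.023). Entpd2, an ectonucleotidase, rose by 0.77 (SE 0.10, adjusted p = 0.032), Tmem119 by 0.64 (adjusted p = 0.032) and Ctsh, a lysosomal protease, by 0.50 (adjusted p = 0.036). All 10 had the same direction in both mice. Tested directly, 0 genes differed in guide effect between these cells and heterozygous cells without Cas9. Adam33 and Tmem119 were also higher with the guides in those heterozygous cells, without passing. Dependence of the 10 on Cas9 or the Pro allele was therefore not shown by that contrast. Against wild-type Cas9 cells Adam33 had a more positive guide effect (log2 difference 0.86, SE 0.10, adjusted p = 0.032). That difference did not pass with only the compared genotypes in the fit. These were 10 higher and 0 lower genes by limma, with 1055 genes at an unadjusted p under 0.05, and 8 higher genes by limma voom. In homozygous Cas9 cells the count was 0 without the mouse as a block and 0 with only this genotype's libraries. It was 1 without the gLmna-2 library of replicate 2, 2 without gMock or gLmna-2 of replicate 1, 6 without gLmna-1 of replicate 2 and 152 without gLmna-1 of replicate 1.

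Among the fixed gene lists in homozygous Cas9 cells, senescence and secretory factors had a median log2 change of 0.45, with 21 of 25 members positive and none past the test over all genes. Adjusted over the list alone, 2 passed: Cdkn2a, a cell cycle inhibitor locus, at 90.7 ± 30.6 FPKM (SD, n = 2) under gMock and 127 ± 24.1 (n = 4) with the guides, and Ccl8, a chemokine, at 20.2 ± 5.99 and 57.2 ± 33.5. The list test gave adjusted p = 1.5e-06 by camera, adjusted p = 0.11 with an estimated correlation and 0.048 by fry. Pigment and Schwann cell markers had a median of 0.41 with 7 of 7 positive, and 4 passed adjusted over the list alone, including Erbb3 at 0.617 ± 0.690 and 1.27 ± 0.719 FPKM. The camera test of these gave adjusted p = 7.4e-06, adjusted p = 0.21 with an estimated correlation and 0.048 by fry. The interferon response list had a median of −0.39 with 2 of 28 positive (camera 4.8e-09, adjusted p = 0.43 with an estimated correlation), and Isg15, a ubiquitin-like antiviral protein, was at 29.0 ± 13.9 and 14.5 ± 8.94 FPKM. The mean of this list (log2) was 2.20 under gMock, 1.69 under gLmna-1 and 2.57 under gLmna-2 in replicate 1, and 2.80, 1.82 and 2.18 in replicate 2, so that gLmna-2 was above gMock in replicate 1. Cell cycle genes had a median of −0.34 with 0 of 34 positive (camera 4.2e-05, adjusted p = 0.56 with an estimated correlation), and Mki67, a proliferation marker, was at 4.15 ± 0.386 and 2.74 ± 0.750 FPKM. Contractile genes had a median of 0.36 with 14 of 14 positive (camera 0.00024, adjusted p = 0.43 with an estimated correlation), and Tagln was at 504 ± 154 and 671 ± 188 FPKM. Immune markers had a median of 0.34 with 12 of 12 positive (camera 0.0075, adjusted p = 0.56 with an estimated correlation), and Lyz2, the macrophage lysozyme, was at 509 ± 79.6 and 779.8 ± 373.9 FPKM. The mean of the immune list (log2) was 4.41 under gMock, 4.10 under gLmna-1 and 5.42 under gLmna-2 in replicate 1, and 4.61, 5.22 and 4.64 in replicate 2. The contractile list was at 6.07, 5.97 and 6.45 in replicate 1 and at 5.43, 5.99 and 5.87 in replicate 2.

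Extracellular matrix genes in homozygous Cas9 cells had a median log2 change of 0.12 (camera 0.0099, adjusted p = 0.43 with an estimated correlation), and Loxl1, a matrix cross-linking enzyme, passed adjusted over the list alone at 48.6 ± 23.8 FPKM (SD, n = 2) and 69.7 ± 23.8 (n = 4). Lamins and nuclear envelope genes had a median of −0.07 (camera 0.0070, adjusted p = 0.36 with an estimated correlation), and Nup153, a nuclear basket protein, passed adjusted over the list alone at 13.8 ± 1.35 and 11.01 ± 1.55 FPKM. NF-kB genes had a median of 0.31 (camera 0.024, adjusted p = 0.43 with an estimated correlation) and cartilage and bone markers −0.29 (camera 0.024, adjusted p = 0.34 with an estimated correlation), with 0 calls in either list. Medians of the lists that did not pass were −0.03 for p53 targets, −0.05 for NRF2 targets, −0.02 for the unfolded protein response, 0.00 for posterior Hox genes, 0.04 for fibroblast markers and 0.04 for adipocyte markers. Camera gave these adjusted p = 0.36, 0.13, 0.94, 0.93, 0.098 and 0.72. Hoxb13 and the fibroblast marker Thy1 passed adjusted over their lists alone, Thy1 at 38.3 ± 5.14 and 91.1 ± 50.9 FPKM. Skeletal muscle, keratinocyte and endothelial markers had 4, 4 and 2 measured members, too few for a set test, and medians of 0.20, −0.11 and 0.28, with 1 endothelial gene past the threshold adjusted over the list alone. The unfolded protein response list had a negative median and a positive direction by fry.

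**Figure D2:**
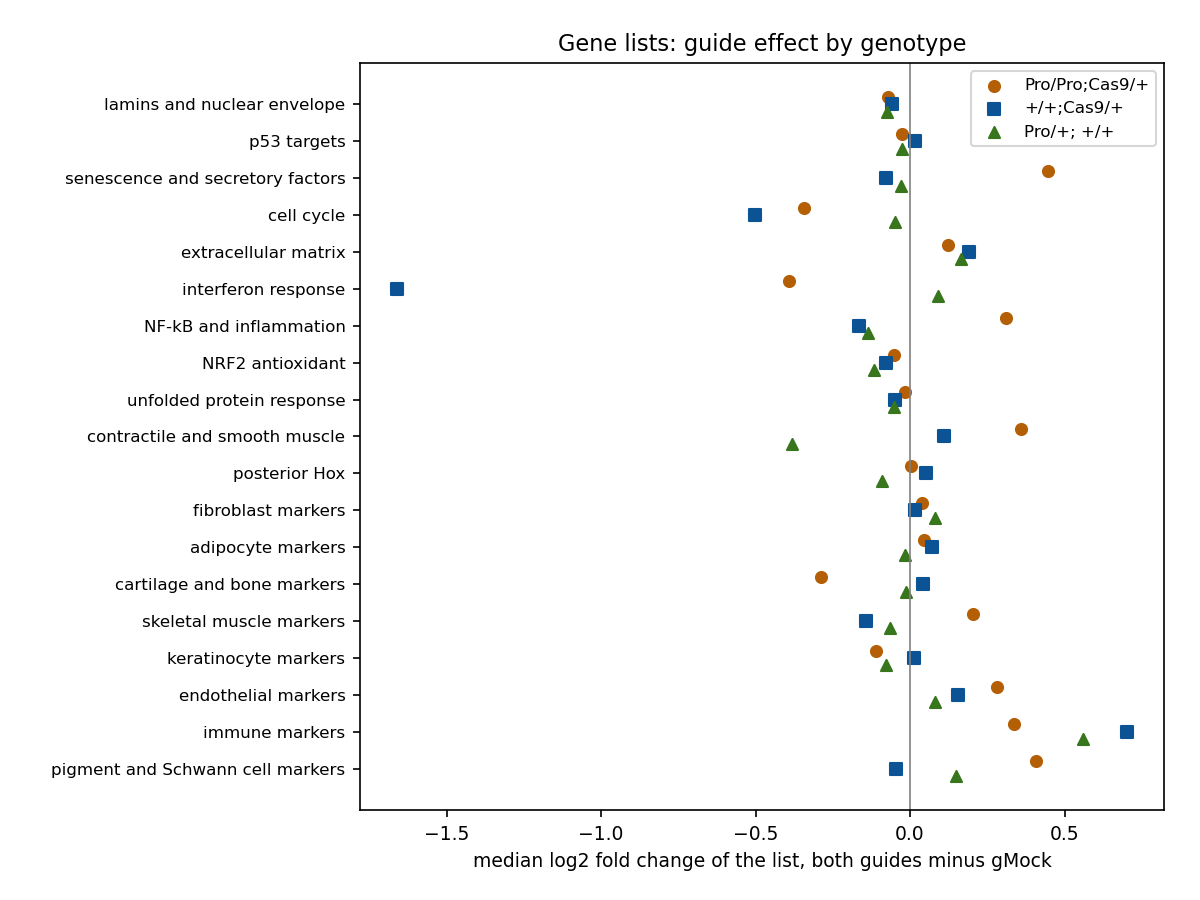
Median log2 change of each gene list, both Lmna guides minus gMock, in the 3 genotypes, with a point for each list and genotype. The interferon response list lies at −1.66 in wild-type Cas9 cells, −0.39 in homozygous Cas9 cells and 0.09 in heterozygous cells without Cas9.

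The guides were also compared with each other in homozygous Cas9 cells. Values are given for gLmna-2 against gLmna-1. Among p53 targets Pmaip1, a pro-apoptotic factor, was at 28.6 ± 6.10 against 6.68 ± 3.54 FPKM (SD, n = 2 each; log2 difference 2.01, SE 0.22, adjusted p = 0.0030). Mdm2, the p53 ubiquitin ligase, was at 119 ± 11.6 against 62.9 ± 0.807 (0.90, SE 0.09, adjusted p = 0.0030), and Perp at 11.05 ± 1.67 against 2.39 ± 0.470 (1.83, SE 0.33, adjusted p = 0.013). The chemokine Cxcl1 was at 19.6 ± 0.0907 against 92.5 ± 9.76 (−2.18, SE 0.31, adjusted p = 0.0063) and the chemokine Ccl2 at 224 ± 16.2 against 560.3 ± 128 (−1.300, SE 0.23, adjusted p = 0.011). Another chemokine, Ccl8, was at 98.3 and 67.7 FPKM in the libraries with gLmna-2 and at 42.2 and 20.6 in those with gLmna-1. The metalloprotease Mmp10 was at 22.6 ± 17.0 against 2.25 ± 0.451 (2.65, SE 0.41, adjusted p = 0.0076) and Mmp13 at 265 ± 143 against 577 ± 288 (−1.14, SE 0.19, adjusted p = 0.0093). Prrx1, a mesenchymal transcription factor, was at 42.99 ± 0.696 against 16.9 ± 1.42 (1.303, SE 0.20, adjusted p = 0.0079), and Thy1 at 122 ± 51.03 against 60.6 ± 38.2 (1.08, SE 0.20, adjusted p = 0.014). Of the unfolded protein response list Calr, a chaperone of the endoplasmic reticulum, was at 791 ± 74.3 against 1239.8 ± 7.44 (−0.65, SE 0.13, adjusted p = 0.017) and Manf at 59.7 ± 0.893 against 89.4 ± 5.12 (−0.57, SE 0.08, adjusted p = 0.0065). Col11a1, a cartilage collagen, was at 17.8 ± 0.601 against 51.7 ± 4.42 (−1.49, SE 0.17, adjusted p = 0.0034), and Tnc, tenascin C of the matrix, at 251 ± 4.39 against 126 ± 19.6 (1.00, SE 0.16, adjusted p = 0.0086). These list members were named after the data had been seen, by the rule fixed for the main comparisons.

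In that comparison of guides 1253 genes passed, 872 of them higher with gLmna-2. The count was 140 without the gLmna-2 library of replicate 1, 238 without that of replicate 2 and 2631 without the gLmna-1 library of replicate 1. It was 59 without the mouse as a block and 0 with only the libraries of homozygous Cas9 cells. Of 28 p53 targets, 4 were higher and 1 lower (6 and 2 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.060, fry 0.025). The p53 list did not pass camera with an estimated correlation either. Of 19 unfolded protein response genes, 7 were lower and 0 higher (0 and 10 higher and lower adjusted over the list alone), with a median of −0.45 (camera 2.2e-06, adjusted p = 0.30 with an estimated correlation, fry 0.025). Of 29 matrix genes, 4 were higher and 10 lower (5 and 16 adjusted over the list alone), with a median of −0.42 (camera 4e-05, adjusted p = 0.30 with an estimated correlation, fry 0.045). Senescence and secretory factors had 3 higher and 8 lower of 25, with the same counts adjusted over the list alone (camera 0.018, adjusted p = 0.34 with an estimated correlation). The interferon response list had a median of 0.50 with 28 of 28 positive and 1 called, Xaf1 (none adjusted over the list alone; camera 0.00044, adjusted p = 0.55 with an estimated correlation). NRF2 targets had a median of 0.41 with 2 called, Gclc and Nqo1 (2 adjusted over the list alone; camera 0.0043, adjusted p = 0.46 with an estimated correlation). Fibroblast markers had a median of 0.29 with 3 higher (camera 0.032, adjusted p = 0.40 with an estimated correlation, fry 0.025), and cartilage and bone markers −0.48 with 1 higher and 4 lower (camera 0.015, adjusted p = 0.30 with an estimated correlation, fry 0.032). Pigment and Schwann cell markers had a median of 0.47 (6 higher adjusted over the list alone; camera 0.018, adjusted p = 0.40 with an estimated correlation, fry 0.025). Cell cycle genes had a median of −0.25 (camera 0.029, adjusted p = 0.83 with an estimated correlation). Medians of lamins at 0.05 and of posterior Hox genes at 0.04 turned negative under both rescalings, and those lists did not pass. The median of immune markers was 0.58 in the same comparison (camera 0.50), and Lyz2 was at 358 and 1224 FPKM with gLmna-1 and gLmna-2 in replicate 1 and at 918 and 620.3 in replicate 2.

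Against gMock, gLmna-1 changed 76 genes upward and 47 downward in homozygous Cas9 cells. Among list members, Cxcl1 rose from 24.8 ± 4.26 to 92.5 ± 9.76 FPKM (SD, n = 2 each; log2 change 1.86, SE 0.31, adjusted p = 0.039). Ccl2 rose from 240.1 ± 28.3 to 560.3 ± 128 (1.21, SE 0.23, adjusted p = 0.047) and Vcam1, an adhesion molecule, from 28.6 ± 13.9 to 54.5 ± 5.88 (0.99, SE 0.18, adjusted p = 0.047). Loxl1 rose from 48.6 ± 23.8 to 85.6 ± 21.6 (0.87, SE 0.13, adjusted p = 0.030), and Mdm2 fell from 99.2 ± 6.63 to 62.9 ± 0.807 (−0.65, SE 0.09, adjusted p = 0.027). With gLmna-2, 44 genes were higher and 1 lower, among them Thy1, from 38.3 ± 5.14 to 122 ± 51.03 (1.58, SE 0.20, adjusted p = 0.022), and Ccl8, from 20.2 ± 5.99 to 83.0 ± 21.6 (1.99, SE 0.31, adjusted p = 0.038). Cdkn2a rose with gLmna-1 by 0.46 (SE 0.08, adjusted p = 0.047) and with gLmna-2 by 0.54 (SE 0.08, adjusted p = 0.038). The gLmna-1 count of 123 was 0 without gMock of replicate 2, 3 without gLmna-1 of replicate 2, 51 without either gLmna-2 library and 1773 without gLmna-1 of replicate 1. The gLmna-2 count of 45 was 0 without gMock of replicate 1 or either gLmna-2 library, 11 without gMock of replicate 2 and 181 without either gLmna-1 library, and both counts were 0 without the mouse as a block.

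In wild-type Cas9 cells, where Lmna is not mutant, interferon-stimulated genes were lower with the guides than under gMock. Isg15 fell from 195 ± 8.22 FPKM (SD, n = 2) to 19.3 ± 7.67 (n = 4; log2 change −3.35, SE 0.38, adjusted p = 0.0047). Ifit1, which binds viral RNA, fell from 95.5 ± 5.69 to 10.9 ± 6.95 (−3.18, SE 0.50, adjusted p = 0.019), and Usp18, the protease that removes ISG15, from 32.6 ± 1.67 to 3.46 ± 1.68 (−2.99, SE 0.37, adjusted p = 0.0057). Ifi44 fell from 43.5 ± 3.29 to 5.32 ± 2.36 (−2.89, SE 0.34, adjusted p = 0.0049), Oasl2 from 31.2 ± 1.57 to 3.84 ± 1.17 (−2.76, SE 0.30, adjusted p = 0.0042) and Ifit3 from 108 ± 18.6 to 16.7 ± 6.47 (−2.69, SE 0.38, adjusted p = 0.0095). The chemokine Cxcl10 fell from 10.6 ± 3.29 to 0.912 ± 0.458 (−2.61, SE 0.30, adjusted p = 0.0047), and Bst2, which tethers budding virus, from 236 ± 3.52 to 48.1 ± 12.8 (−2.31, SE 0.21, adjusted p = 0.0031). The transcription factor gene Irf7 fell by 2.31 (SE 0.29, adjusted p = 0.0062). Of 28 interferon response genes, 26 passed lower (28 adjusted over the list alone), and the median was −1.66 (camera 4.9e-59, adjusted p = 0.082 with an estimated correlation, fry 0.0030). H2-K1 and B2m, which encode parts of class I antigen presentation and were picked outside the lists, fell, H2-K1 from 138 ± 18.6 to 77.1 ± 20.7 and B2m from 1452 ± 106 to 761 ± 226 (adjusted p = 0.0034 and 0.0086).

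Other genes passed in wild-type Cas9 cells too. Tor1aip1, a lamin-binding protein of the inner nuclear membrane, fell from 41.2 ± 1.91 FPKM (SD, n = 2) to 26.5 ± 2.17 (n = 4; −0.62, SE 0.10, adjusted p = 0.025), Igf2, a growth factor, by 1.04 (SE 0.11, adjusted p = 0.0042), Penk, the enkephalin precursor, by 0.85 (adjusted p = 0.0062) and Agrn, a heparan sulphate proteoglycan, by 1.01 (adjusted p = 0.024). The 3 higher genes were Spon1, a matrix protein, from 5.26 ± 1.27 to 9.41 ± 1.76 (0.73, SE 0.13, adjusted p = 0.031), Tmem234 (0.40, SE 0.07, adjusted p = 0.046) and the small nucleolar RNA Snord95 (1.39, SE 0.25, adjusted p = 0.044), the last named after its value was seen. In all 3 genes were higher and 104 lower. The count of 107 was 0 without either gMock library, 56 without gLmna-2 of replicate 2 and 67 without gLmna-1 of replicate 1, and 67 with only the libraries of wild-type Cas9 cells.

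**Figure D3:**
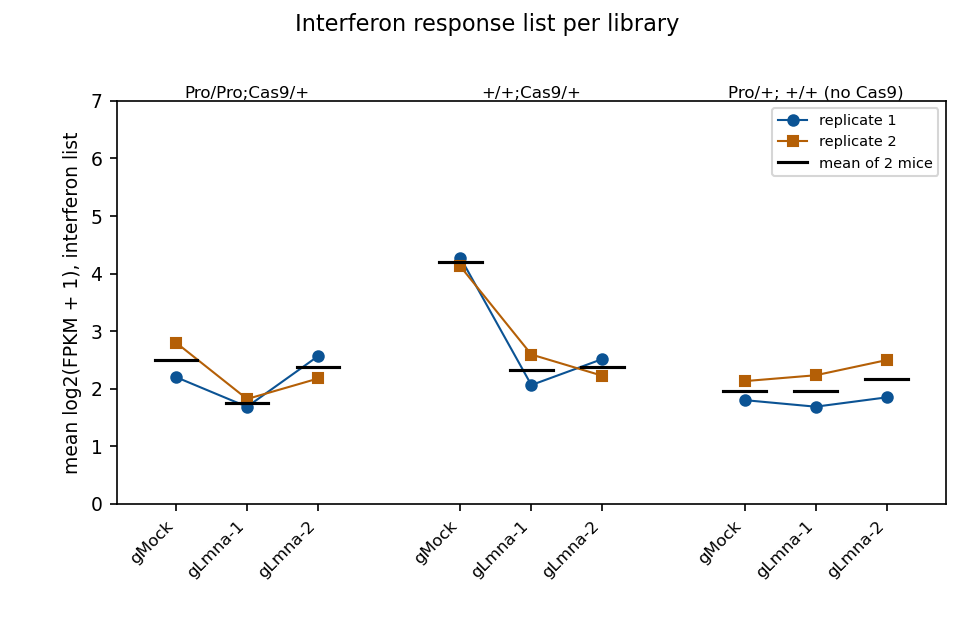
Mean log2(FPKM + 1) of the interferon response list in each library, by genotype and guide, with points for libraries, lines joining those of the same mouse and black bars for means of 2 mice. The gMock libraries of wild-type Cas9 cells lie at 4.28 and 4.13, and the other 16 libraries at 1.69 to 2.80.

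Among the other lists in wild-type Cas9 cells, cell cycle genes had a median log2 change of −0.50 with 0 of 34 positive (camera 7.6e-07, adjusted p = 0.69 with an estimated correlation), but the mice differed. In replicate 1 the mean of this list was 2.15 (log2) under gMock and 3.07 and 1.94 with gLmna-1 and gLmna-2, and in replicate 2 it was 3.59, 2.32 and 2.16, so the negative median rests on the gMock library of replicate 2. Matrix genes had a median of 0.19 with 23 of 29 positive (camera 5.6e-06, adjusted p = 0.32 with an estimated correlation) and 0 calls, with none adjusted over the list alone. Immune markers had a median of 0.70 with 11 of 12 positive (camera 8.4e-07, adjusted p = 0.46 with an estimated correlation), and Lyz2 was at 121 ± 101 FPKM under gMock (SD, n = 2) and 238 ± 112 with the guides (n = 4). Lamins and nuclear envelope genes had a median of −0.06 with 1 lower (3 adjusted over the list alone; camera 0.0019, adjusted p = 0.32 with an estimated correlation). Ccl5, an interferon-induced chemokine, was the single call in the NF-kB list. Medians and means differed in sign for cartilage and bone markers, 0.04 and −0.16, for adipocyte markers, 0.07 and −0.01, and for p53 targets, 0.02 and −0.02, and the first of these medians turned negative under quantile normalization. With a single guide, gLmna-1 changed 3 genes upward and 84 downward and gLmna-2 3 and 68, and between the guides 0 genes passed by limma (1009 at an unadjusted p under 0.05, 0 by limma voom). The gLmna-1 count of 87 was 0 without either gMock library or gLmna-1 of replicate 1 and 45 without gLmna-1 of replicate 2. The gLmna-2 count of 71 was 0 without gMock or gLmna-2 of replicate 2, 6 without gLmna-2 of replicate 1, 131 without gMock of replicate 1 and 43 without the mouse as a block. With only the wild-type libraries in the fit, gLmna-1 gave 21 genes and gLmna-2 gave 0.

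Heterozygous cells without Cas9 served as the negative control for the guides. No gene passed: limma called 0 genes, with 397 at an unadjusted p under 0.05, and limma voom 0. The 397 are a smaller share of the 12599 tested genes than the 0.05 that arises with no effect. The fit used a single spread per gene for all genotypes. Such a fit is too strict in heterozygous cells, and too lenient in the others, if heterozygous libraries vary less. The spreads were not compared, so counts in these cells and in Cas9 cells may not be on an equal footing. The 5 genes with the smallest p did not pass. They were Matn2, a matrix adaptor protein, at 14.5 ± 6.52 FPKM (SD, n = 2) under gMock and 27.6 ± 15.1 (n = 4) with the guides, Tmem119 at 37.0 ± 10.3 and 50.3 ± 10.1, Adam33 at 8.98 ± 3.70 and 11.98 ± 5.17, the microRNA gene Mir7025 at 1.79 ± 0.569 and 5.16 ± 0.634, and Bag2, a chaperone regulator, at 24.5 ± 5.02 and 18.2 ± 4.60. Single guides also gave 0 calls by limma and by limma voom, with 173 and 566 genes at an unadjusted p under 0.05 for gLmna-1 and gLmna-2 against gMock and 266 between the guides. Matrix genes had a median of 0.16 with 23 of 29 positive (camera 1.1e-09, adjusted p = 0.23 with an estimated correlation), and Postn, a matricellular protein, was at 68.0 ± 47.8 and 158 ± 134 FPKM. The immune marker list had a median of 0.56 with 12 of 12 positive (camera 8.6e-08, adjusted p = 0.46 with an estimated correlation), and contractile genes −0.38 with 1 of 14 positive (camera 0.00012, adjusted p = 0.56 with an estimated correlation). The interferon response list had a median of 0.09 (camera 0.0030, adjusted p = 0.67 with an estimated correlation). NRF2 targets had a median of −0.12 (camera 0.027, adjusted p = 0.62 with an estimated correlation), fibroblast markers 0.08 (camera 0.0026, adjusted p = 0.37 with an estimated correlation) and pigment and Schwann cell markers 0.15 (camera 0.013, adjusted p = 0.46 with an estimated correlation). No list member passed adjusted over its list alone. Medians of p53 targets, senescence factors, adipocyte markers and cartilage markers lay at −0.02, −0.03, −0.02 and −0.01 and turned positive under median-ratio rescaling, the last pair also under quantile normalization.

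Whether guide effects differed between genotypes was tested directly. Between wild-type Cas9 cells and heterozygous cells, 37 genes had a more negative guide effect in wild-type cells and 0 a more positive one, and 10 of the 37 were on the interferon list. Interferon-inducible genes such as Iigp1 and Ifi47 are off this list, so 10 is not the number of such genes among the 37. Isg15 differed by −3.75 (log2, SE 0.54, adjusted p = 0.044), Cxcl10 by −2.93 (SE 0.42, adjusted p = 0.044), Bst2 by −2.35 (SE 0.30, adjusted p = 0.042). The interferon-inducible GTPase genes Iigp1 and Ifi47 differed by −2.48 and −1.92 (adjusted p = 0.042 for both), Herc6 by −1.34 (SE 0.14, adjusted p = 0.042) and Igf2 by −1.08 (SE 0.16, adjusted p = 0.044). The interferon list differed by a median of −1.71 (27 of 28 adjusted over the list alone; camera 2e-65, adjusted p = 0.064 with an estimated correlation, fry 0.016). This count was 0 in 11 of the 12 fits that left out a library of these genotypes and 38 without gLmna-1 of wild-type replicate 2. It was 0 with a filter of 5 FPKM, with pseudocounts of 0.1 or 0.5 and without heterozygous replicate 2, and 1 by limma voom. Without the mouse as a block 10 genes passed, and with only these genotypes 66.

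Between homozygous and wild-type Cas9 cells, 6 genes had a more positive guide effect in homozygous cells. They were the complement factor Cfb (1.27, SE 0.12, adjusted p = 0.021), Gm4951 (1.24, SE 0.15), Herc6 (1.14, SE 0.14), Ifitm3, an antiviral membrane protein (1.00, SE 0.12), H2-K1 (0.96, SE 0.12) and Adam33 (0.86, SE 0.10), the last 5 at adjusted p = 0.032. The interferon list differed by a median of 1.29 with no call over all genes (27 of 28 adjusted over the list alone; camera 1.9e-53, adjusted p = 0.058 with an estimated correlation, fry 0.069). Senescence and secretory factors differed by a median of 0.24 with 24 of 25 positive (1 adjusted over the list alone; camera 2.5e-06, adjusted p = 0.058 with an estimated correlation). The count of 6 was 0 without gMock or gLmna-2 of homozygous replicate 1 or without any of the 6 libraries of wild-type Cas9 cells, 11 without gLmna-1 of homozygous replicate 1, 14 without gMock or gLmna-1 of homozygous replicate 2 and 22 without gLmna-2 of homozygous replicate 2. It was 3 without the mouse as a block and 0 with only these genotypes.

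Between homozygous Cas9 cells and heterozygous cells limma called 0 genes, with 523 at an unadjusted p under 0.05, and limma voom 0. The smallest p belonged to Adam33 (0.76, SE 0.10, adjusted p = 0.48), and Sfrp1, Serping1, Lrrc27 and Frzb differed by 0.95, 0.75, 0.81 and 0.92 without passing. Contractile genes differed by a median of 0.74 with 14 of 14 positive (3 adjusted over the list alone; camera 3.2e-08, adjusted p = 0.40 with an estimated correlation). The interferon list differed by −0.45 (camera 1.5e-13, adjusted p = 0.40 with an estimated correlation), senescence factors by 0.28 (camera 0.00093, adjusted p = 0.39 with an estimated correlation) and cell cycle genes by −0.28 (camera 1.3e-05, adjusted p = 0.57 with an estimated correlation).

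Genotypes were compared under gMock, with the mouse as the replicate. In homozygous against wild-type Cas9 cells, Ccl8 was at 20.2 ± 5.99 against 464 ± 272 FPKM (SD, n = 2 each; log2 difference −4.35, SE 0.43, adjusted p = 0.037). Cck, the cholecystokinin precursor, was at 38.7 ± 27.2 against 605 ± 163 (−4.10, SE 0.49, adjusted p = 0.047), Dpt, a dermal matrix protein, at 10.0 ± 3.27 against 122 ± 35.2 (−3.49, SE 0.33, adjusted p = 0.037) and Thy1 at 38.3 ± 5.14 against 381.3 ± 113 (−3.26, SE 0.37, adjusted p = 0.042). Oasl2 was at 2.17 ± 0.697 against 31.2 ± 1.57 (−3.36, SE 0.26, adjusted p = 0.028), Syt13 differed by −3.22 (adjusted p = 0.037) and Iigp1 by −2.66 (adjusted p = 0.028). Differences below these included Pla2g2e, a secreted phospholipase, at −2.58 (adjusted p = 0.034), Gsta4, a glutathione transferase, at −2.05 (adjusted p = 0.044) and Pdgfra, a mesenchymal growth factor receptor, at −1.16 (adjusted p = 0.037). Cdsn, corneodesmosin, was the single higher gene, at 33.8 ± 9.35 against 6.87 ± 2.29 (2.15, SE 0.26, adjusted p = 0.049). Lmna differed by −0.21 (SE 0.22, adjusted p = 0.96). The interferon list had a median of −1.71 with 3 of 28 lower (27 adjusted over the list alone; camera 1.5e-35, adjusted p = 0.21 with an estimated correlation, fry 0.038). The wild-type gMock libraries stood apart in this list, at means of 4.28 and 4.13 (log2) where the other 16 libraries lay at 1.69 to 2.80. In libraries with gLmna-1 and gLmna-2, compared after this was seen, wild-type minus homozygous Cas9 cells had medians of 0.52 and −0.04. Fibroblast markers had a median of −0.56 with 3 of 12 lower (5 adjusted over the list alone; camera 1.1e-07, adjusted p = 0.21 with an estimated correlation, fry 0.038).

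Cartilage and bone markers in the same contrast had a median of 1.53 with 9 of 10 positive and no call over all genes (7 adjusted over the list alone; camera 5.7e-08, adjusted p = 0.21 with an estimated correlation). Among them Col11a1 was at 37.8 ± 11.1 against 7.91 ± 4.90 FPKM (SD, n = 2 each), Alpl, alkaline phosphatase, at 9.37 ± 3.61 against 1.56 ± 0.419, and Spp1, osteopontin, at 4939.9 ± 535 against 1573 ± 4.66. Immune markers had a median of 2.02 with 12 of 12 positive (none adjusted over the list alone; camera 8.4e-09, adjusted p = 0.46 with an estimated correlation), and Lyz2 was at 509 ± 79.6 against 121 ± 101. Posterior Hox genes had a median of 0.36 (3 adjusted over the list alone; camera 0.011, adjusted p = 0.50 with an estimated correlation). With a block for the style of sample names, which follows the replicate number in every genotype, 0 genes passed in this contrast. Without that block, in all 1 gene was higher and 49 were lower in homozygous Cas9 cells. Their count of 50 was 0 without gMock of homozygous replicate 1 or of either wild-type replicate and 2 without that of homozygous replicate 2, and in the gLmna-1 and gLmna-2 libraries the same contrast gave 304 and 1.

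By their labels, heterozygous cells differ from wild-type Cas9 cells by the Pro allele and by the absence of Cas9. Under gMock heterozygous replicate 2 also had the Y-linked gene Ddx3y at 19.4 FPKM and Xist at 0.00428. The wild-type mice had Xist at 23.2 and 27.5. The contrast of heterozygous against wild-type cells therefore also holds a difference in sex. Alpl was at 22.7 ± 2.41 against 1.56 ± 0.419 FPKM (SD, n = 2 each; log2 difference 3.22, SE 0.27, adjusted p = 0.029). Steap4, a metalloreductase, was at 7.82 ± 0.832 against 0.334 ± 0.251 (2.73, SE 0.22, adjusted p = 0.029), Cxcl5, a neutrophil chemokine, at 339 ± 127 against 48.9 ± 5.55 (2.72, SE 0.29, adjusted p = 0.029) and Cdsn at 34.1 ± 1.61 against 6.87 ± 2.29 (2.19, SE 0.26, adjusted p = 0.043). Lower genes included Ifit1 at 4.86 ± 2.47 against 95.5 ± 5.69 (−4.11, SE 0.42, adjusted p = 0.029), Ifit3 (−3.95, adjusted p = 0.029), Oasl2 (−3.78, adjusted p = 0.025), Usp18 (−3.62, adjusted p = 0.029), Bst2 at 33.8 ± 4.58 against 236 ± 3.52 (−2.78, SE 0.28, adjusted p = 0.029) and Acta1, skeletal muscle actin, at 10.7 ± 0.867 against 45.9 ± 10.3 (−1.99, SE 0.17, adjusted p = 0.029). Lmna differed by −0.54 (SE 0.22, adjusted p = 0.41). The interferon list had a median of −1.95 with 11 of 28 lower (27 adjusted over the list alone; camera 4.6e-36, adjusted p = 0.50 with an estimated correlation, fry 0.034). This list was set apart by the same wild-type gMock libraries, and with gLmna-1 and gLmna-2 wild-type minus heterozygous cells had medians of 0.37 and 0.21. Fibroblast markers lay at −0.69 (5 lower adjusted over the list alone; camera 0.00013, adjusted p = 0.50 with an estimated correlation) and cartilage and bone markers at 0.76 with 1 higher (2 adjusted over the list alone; camera 0.0024, adjusted p = 0.69 with an estimated correlation). The immune marker list had a median of 0.22 (camera 0.23). In all 4 genes were higher and 48 lower, and the count of 52 was 3 without gMock of heterozygous replicate 1 and 0 without that of any of the other 3 mice. With a block for the style of sample names 0 genes passed in this contrast too. The contrasts against wild-type Cas9 cells share the same gMock libraries, so their gene lists were not compared with each other.

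Homozygous Cas9 cells against heterozygous cells gave 0 genes by limma, with 547 at an unadjusted p under 0.05, and 0 by limma voom. This contrast also holds the presence of Cas9 and, through heterozygous replicate 2, a difference in sex. Homozygous replicates 1 and 2 had Xist at 23.7 and 24.4 FPKM under gMock. Cxcl5 was at 63.0 ± 13.4 against 339 ± 127 FPKM (SD, n = 2 each; log2 difference −2.37, adjusted p = 0.74), Serping1 at 14.4 ± 2.63 against 59.2 ± 10.4 (−1.97, adjusted p = 0.74), Steap4 at 1.62 ± 0.496 against 7.82 ± 0.832 (−1.76, adjusted p = 0.74), and H2bc1, a histone gene, was at 2.12 ± 0.450 in homozygous cells and listed at 0 in heterozygous cells. Lmna differed by 0.33 (adjusted p = 0.97). Immune markers had a median of 1.70 with 11 of 12 positive (camera 1.7e-07, adjusted p = 0.65 with an estimated correlation), the interferon list 0.41 (camera 4.2e-10, adjusted p = 0.65 with an estimated correlation) and p53 targets 0.13 (camera 0.0086, adjusted p = 0.74 with an estimated correlation). The immune list had means (log2) of 4.41 and 4.61 in homozygous replicates 1 and 2 and of 3.78 and 2.31 in heterozygous replicates 1 and 2. Senescence factors had a median of 0.02 and a mean of −0.26, with 4 lower adjusted over the list alone (camera 0.029 downward, adjusted p = 0.65 with an estimated correlation). Without gMock of heterozygous replicate 1 this contrast called 3 genes.

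Whether the guides moved homozygous Cas9 cells toward or away from wild-type Cas9 cells was examined by correlating, across 12599 genes, the guide effect in 1 homozygous mouse with the genotype difference taken from the other mouse, so that no library was shared. The genotype difference was homozygous minus wild-type, so a negative correlation means guide effects toward wild-type cells. The correlation was −0.117 (covariance −0.0115) for the guide effect of replicate 1 and 0.347 (covariance 0.0460) for that of replicate 2, of opposite sign. Both genotype differences used the same wild-type gMock libraries, so these correlations are not independent. Those libraries are the ones set apart in the interferon list. Simulated data with no effect gave −0.0034 with an SD of 0.020 over 100 simulations. All genes were drawn independently in these simulations, so this SD is too narrow a scale where genes vary together. With gLmna-1 alone the values were −0.068 and 0.539, and with gLmna-2 alone −0.107 and −0.237. With shared gMock libraries the correlation was −0.207 (covariance −0.0150), against −0.435 (covariance −0.0201) in simulations without an effect, a covariance difference of 0.0051. Genes are not independent replicates, so no p-value was computed.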

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

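The tests of the interferon pattern in this part were all chosen after the result was seen. The guide effect differed for 37 genes between wild-type Cas9 cells and heterozygous cells and for 6 genes between homozygous and wild-type Cas9 cells, by a test of the difference itself. The 37 were 0 with a filter of 5 FPKM, with pseudocounts of 0.1 or 0.5, without heterozygous replicate 2 and in 11 of 12 fits with a library left out, and the 6 were 0 with only these genotypes. Isg15, on the interferon list, was at 189 and 201 FPKM in the gMock libraries of wild-type Cas9 cells. The list's mean lay at 4.28 and 4.13 (log2) in these libraries and at 1.69 to 2.80 in the other 16.

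Against immune cells in those 2 cultures, the immune marker list had a median log2 change of 0.703 from gMock to the guides in wild-type Cas9 cells, opposite to the interferon list at −1.66. Against a difference present in wild-type cells under every treatment, the interferon list in the guide libraries differed from the other genotypes by medians of 0.52, 0.37, −0.04 and 0.21. The smallest, −0.043, was against homozygous Cas9 cells with gLmna-2. What stays open is a difference in culture or transduction conditions, which could have acted on these 2 libraries. No day, density or vector dose is recorded for the 2, a number that the design fixes and that tests nothing, so these conditions stayed untested, as did an effect of gMock in wild-type Cas9 cells. Apart from immune cells and a difference of wild-type cells under every treatment, no biological explanation was tested.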

How the results depend on the processing

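The analysis and its alternatives were chosen before the data were examined, except for limma voom, all parts of a symbol together, the genotype contrasts in guide libraries, the fits without heterozygous replicate 2 or without the interferon list, and the work on Lmna parts. These were chosen after the data were seen. Results are counts of genes past the threshold. In the order used below they were 10, 0 and 107 for the guides in homozygous, heterozygous and wild-type Cas9 cells, 123, 45 and 1253 for gLmna-1, gLmna-2 and their difference in homozygous cells, 87 and 71 for gLmna-1 and gLmna-2 in wild-type cells, 37 and 6 for differences of guide effects, and 50, 52 and 0 for genotypes. The cause of a change was not tested unless stated. Of 1637 values of 78 results of named genes other than Lmna, which is given below, 866 were the same, 275 weaker and 6 reversed, and of those with a library left out 196 were the same and 294 weaker.

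The block for the mouse was changed in 3 ways. Without the replicate block the guides called 0 genes in homozygous Cas9 cells, gLmna-1 and gLmna-2 called 0 each, and the guides differed in 59 genes. Without this pairing gLmna-2 called 43 in wild-type cells, and the differences of guide effects 10 and 3. With the mouse as a random effect the counts in homozygous cells were 1 for the guides, 1 for gLmna-1, 5 for gLmna-2 and 795 between guides, and the differences of guide effects gave 58 and 17. With only the compared genotypes and the block, the counts in homozygous cells were 0 for the guides, 0 for gLmna-1, 0 for gLmna-2 and 0 between guides. In wild-type cells they were 67, 21 and 0, and the differences of guide effects gave 66 and 0.

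With no filter on low values the counts were 1 for the guides in homozygous cells, 6 for gLmna-1, 19 for gLmna-2, 27 for gLmna-2 in wild-type cells and 6 for the first difference of guide effects. In heterozygous cells they were 1 and 1 for the single guides and 3 between them, and genotypes gave 2, 15 and 7. A filter of 5 FPKM gave 216 genes for gLmna-1 in homozygous cells and 0 for the first difference of guide effects. With every transcript as its own feature, the guides called 167 genes in wild-type cells, gLmna-1, gLmna-2 and their difference 296, 75 and 2365 in homozygous cells, and gLmna-2 107 in wild-type cells. The second difference of guide effects gave 11 and homozygous against wild-type cells 79.

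A pseudocount of 0.1 gave 33 genes for gLmna-2 in wild-type cells and 0 for the first difference of guide effects, and a pseudocount of 0.5 gave 0 for the latter. Quantile normalization gave 18 for gLmna-2 in homozygous cells and 7 for the first difference. Median-ratio rescaling gave 8 and 1 for the differences of guide effects and 32 for homozygous against wild-type cells. Without the trend gLmna-1 called 50 in homozygous cells and the second difference 10. By limma voom gLmna-1 called 193, the first difference 1, and homozygous against wild-type cells 31. Leaving the interferon list out gave 39 for gLmna-2 in wild-type cells and 7 for the first difference, and leaving heterozygous replicate 2 out gave 0 for that difference.

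For genotypes, all 18 libraries with a random mouse effect gave 452 and 538 genes against wild-type cells for homozygous and heterozygous cells, a block for the style of names 0 and 0, and means per mouse 183 for heterozygous cells. In gLmna-1 libraries the counts were 304 and 86, and in gLmna-2 libraries 1 and 107. In gLmna-1 libraries homozygous minus heterozygous values were reversed for Lmna (−0.19), Cxcl5 (0.16), Steap4 (0.27) and Ccl2 (0.34). In gLmna-2 libraries heterozygous minus wild-type values were reversed for Ifit3b (0.10), Ddx58 (0.035) and Rtp4 (0.072).

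Lmna was reversed in heterozygous cells under median-ratio rescaling (0.021) and without heterozygous replicate 2 (0.013), and between the guides in wild-type cells under quantile normalization (−0.073). With each library left out in turn, the log2 change of Lmna lay at −0.51 to 0.013 for the guides in homozygous cells, −0.70 to −0.047 for gLmna-1, −0.38 to 0.14 for gLmna-2 and −0.076 to 0.58 between guides. The −0.70 and 0.58 passed, both without gLmna-1 of homozygous replicate 1. In heterozygous cells Lmna lay at −0.12 to 0.065 for the guides and −0.041 to 0.33 for gLmna-1, and between guides in wild-type cells at −0.089 to 0.15. For the differences of guide effects it lay at −0.48 to 0.041 for homozygous minus heterozygous cells and −0.29 to 0.24 for homozygous minus wild-type cells, and for homozygous against wild-type cells at −0.50 to 0.088.

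Counts with each library left out ranged from 1 to 152 for the guides in homozygous cells and 0 to 84 in wild-type cells. They ranged from 0 to 1773 for gLmna-1, 0 to 181 for gLmna-2 and 140 to 2631 between guides in homozygous cells, and from 0 to 66 and 0 to 131 for gLmna-1 and gLmna-2 in wild-type cells. The differences of guide effects ranged from 0 to 38 and 0 to 22, and genotypes from 0 to 2, 0 to 3 and 0 to 3. Libraries that changed a count are named beside it in the sections above, or given there as a number of fits. Libraries that ended the call of a single named gene are not listed. For single guides and genotypes the lowest counts came without a gMock library or a library of that guide. The range for the guides in homozygous cells was set by gLmna-2 of replicate 2 (1) and gLmna-1 of replicate 1 (152).

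Of the 16 gene lists, camera with an estimated correlation called 0 in all 18 comparisons. With a correlation of 0.01 it had called 10, 7 and 5 for the guides in homozygous, heterozygous and wild-type cells. The fry test called 2, 0 and 1 for these, 1 and 1 for single guides in homozygous cells and 6 between them, 0, 0 and 0 in heterozygous cells, and 1, 1 and 3 in wild-type cells. It called 0, 1 and 0 for the differences of guide effects and 2, 1 and 0 for genotypes. The correlation of guide and genotype effects was −0.237 with gLmna-2 alone and guides of replicate 2, against 0.347.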

Other observations

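Some genes separated mice within a genotype. Ftl1, a ferritin light chain gene, was at 2.70 to 4.02 FPKM in the libraries of homozygous replicate 1 and at 2.21 to 2.67 in those of heterozygous replicate 1. In homozygous replicate 2 Ftl1 was at 339.6 to 408 FPKM, in heterozygous replicate 2 at 200.5 to 235 and in wild-type Cas9 cells at 337 to 750. Heterozygous replicate 2 had Ddx3y, a Y-linked gene, at 18.4 to 19.4 FPKM and Xist at 0.00428 to 0.0189, where the other 5 mice had Ddx3y at 0 to 0.0213 and Xist at 16.3 to 27.5, so sex differs within the heterozygous group.

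In this part the test of leaving out gLmna-1 of homozygous replicate 2 and the test of 3 prime coverage were written before their results were seen, and the other tests were chosen afterwards. The guides differed from each other in 1253 genes in homozygous Cas9 cells. Without gLmna-1 of homozygous replicate 2 the count was 1180, with 1 gLmna-1 library left in this genotype and the spread taken from the other groups, which argues only against that library alone giving the count. Without a gLmna-2 library, with the same limit, the count was as low as 140, so a gLmna-2 library may decide most of the count. The library gLmna-1 of homozygous replicate 2 lay nearest to a library of heterozygous replicate 1 (r = 0.987), but its Ftl1 was 127 times the highest of that mouse, which argues against an origin in that mouse. It was not alone in lying nearest to another mouse. So did gMock and gLmna-1 of homozygous replicate 1 (r = 0.991 and 0.988, to heterozygous replicate 1). The same held for gLmna-1 of wild-type replicate 1 (r = 0.988, to wild-type replicate 2).

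The exon 12 untranslated region of Lmna was lower against exons 4 to 9 in all 8 guide libraries of Cas9 mice, and no part of Lmna passed a test over all parts. The second of those tests called 0 parts of any gene, so it could hardly have called Lmna. Against a general loss of 3 prime coverage, the last part of 8295 other genes had median log2 changes of 0.16, 0.02, 0.03 and 0.09 in the 4 Cas9 mice, with the lowest at 0.0191, where Lmna exon 12 had −0.64, −0.80, −0.46 and −0.47. The bound written beforehand was within 0.1 of 0 in each mouse, and the value of 0.16 lies outside it on the side opposite to a loss. The rule was therefore changed afterwards to no value below −0.1. Cas9 acting together with the guides may account for the change, but the exact permutation p of 0.0667 is the smallest that 6 mice allow, and genotype differs between the mice with and without Cas9.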
